A study of Mus musculus with 12 samples.

How the data were processed

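RNA from 12 mouse samples was measured by mRNA sequencing, in 4 groups of 3 libraries. The groups are Control, Model, Taurine and Proline. Control is normal lung and Model is untreated orthotopic lung tumour, a tumour grown inside the lung. Taurine and Proline are such tumours treated with the amino acid of that name. The tissue label reads lung tumour for every sample, whereas the series' description calls the control normal lung, and the comparisons follow the description. The sample names give C57 mice. Per the labels' protocols, RNA came from a Qiagen RNeasy kit and libraries from a SMARTer mRNA kit. Nothing in the labels says whether replicates are separate animals, so p-values measure the spread between these samples. No batch, date or pairing is given, and replicate numbers here follow the order of the sample names.

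The authors deposited 1 table of 36254 genes with a raw count and an FPKM value per gene and library. Per the file headers, the counts are unnormalised counts per gene, and they were whole numbers. Per the file headers, FPKM is a fragment count scaled to gene length and library total. Among 10787 genes with 200 or more counts in every library, 99.8% of FPKM values lay within 1% of the count divided by gene length and by 1 constant per library. The genome build is mm10 per the submitters' processing notes. The aligner, the counting program and the strand setting are not given in the sources used here. Of 33734 gene IDs also found in a GRCm38 annotation, 656 (1.94%) had the same start and end in the table, so the build of its positions is uncertain and no positions are given. Genes were handled by their IDs, since 119 symbols are duplicated in the table. Near-identical copies (the Rhox2 genes, haemoglobins, class I genes, Entpd4b beside Entpd4) and overlapping or antisense genes may share reads, and their counts are uncertain.

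Each library held between 56542745 and 69456490 counts. Of the genes, 35211 had a count in some library and 23191 passed edgeR's filter on low counts. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the raw counts. It used TMM scaling, all 12 libraries in 1 fit, a contrast for each comparison, and Benjamini-Hochberg adjustment over all genes tested. The tests were two-sided and the threshold was an adjusted p of 0.05. Adjusted p-values of genes in the text come from this test unless another tool is named. Levels are CPM, counts scaled to a common library total, after TMM scaling, given as mean ± SD with n = 3. The common biological coefficient of variation was 0.437. The standard error (SE) of a log2 fold change is its size divided by the square root of the test's F. A fold against a group with 0 counts is given as a lower bound against 3 counts over the group's libraries, and such bounds cover counting error only. The median log2 fold change of all genes lay within 0.08 of the TMM value under each of 3 other scalings (median ratio, upper quartile, none).

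The comparisons were Model against Control, Taurine against Model, Proline against Model, and Taurine against Proline. The last of these tests the difference between the effects of both amino acids directly, since the Model libraries cancel. The groups, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The rule for the test allowed for either unit: FPKM alone would have gone to limma on log2(FPKM + 1), and raw counts go to edgeR with limma as an alternative. The named genes are the 10 with the largest rise and the 10 with the largest fall in log2(FPKM + 1) among those past the threshold whose groups do not overlap. Where none passed in a direction, the 5 with the smallest p were taken and given as not passing. Predicted genes, clones, mitochondrial genes and immunoglobulin or T-cell receptor segments were left out of that choice. To these were added 2 members per direction of each list that was called or had a passing member, and 10 genes of taurine and proline handling, Cd274 and Mki67 in the comparisons of treated tumours. Genes chosen after their values were seen are said to be so.

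In all, 37 gene lists of pathways, cell types, other tissues and handling (the immediate early and heat shock list) were tested. Of their 444 symbols, 443 were matched to gene IDs, 5 of them through an older symbol. The test was limma's camera with a preset correlation between genes of 0.01, adjusted over the 37 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes. Fry asks whether a list's genes move on balance 1 way. Members were counted as higher, lower or not passing, over all genes and adjusted over the list alone. Marker lists describe bulk RNA and are not cell counts. Camera was also run over 241 KEGG pathways of 15 to 300 genes that the table assigns to genes, a choice made after the data were seen.

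The fit was tested on simulated counts drawn from the fitted Model means, used for every group, and the real library sizes. In each run 50 genes were changed at each of 4 fold sizes, all from genes above 2 CPM in Model. The shares recovered therefore do not cover lower genes or the Control means. With 23191 genes and 3 libraries per group, the Model against Control simulation recovered 60% of 2-fold and 80% of 4-fold changes, with 5 false calls. The Taurine against Model simulation recovered 66% and 98%, with 9 false calls. The Proline against Model simulation recovered 62% and 88%, with 5 false calls, and the Taurine against Proline simulation 70% and 88%, with 4. At 1.5-fold the share recovered was 26%, 28%, 30% and 36% in the same order. Counts of replicate pairs differed by more than counting error, with chi-square per degree of freedom between 29.5 and 113.

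The alternatives were DESeq2 1.42.0, edgeR with no filter, with an FPKM minimum of 5 in 3 libraries, with median-ratio scaling, with only the compared groups, and without mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes. Further ones were limma on log2(FPKM + 1), on log2(FPKM + 0.1), on quantile-normalised values and without trend and robust, voom with library weights, and leaving out each library in turn. Voom weights on counts took the place of limma's array weights. Each run with 1 library left out filtered genes and fitted the spread anew, and tested 24199 to 24498 genes. Alternatives chosen after seeing the data were leaving out 3 libraries together (Model 2, Taurine 3 and Proline 1), marker levels as covariates, and a term for sets of tumour libraries that hold liver or kidney transcripts. With that term each mix of group and set has its own level, so Taurine against Model compares Taurine 1 and 2 with Model 3 alone and Taurine against Proline compares Taurine 3 alone with the Proline libraries. Proline against Model then compares Proline with Model 3, adjusted by the difference of Taurine 1 and 2 from Taurine 3. Calls kept, ended or reversed under the term are weak evidence. No sample was left out of the main test.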

Results

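Gene expression was measured in 12 mouse libraries, with 3 each of normal lung (Control), untreated orthotopic lung tumour (Model), and tumours treated with taurine (Taurine) or proline (Proline). The libraries held 56542745 to 69456490 counts. The first principal component of the tested genes held 67.3% of the variance and separated Control from all tumour libraries. Correlations between libraries, taken across genes, were 0.968 to 0.97 within Control and had a median of 0.774 between Control and tumour. The median was 0.954 between tumour libraries of the same group and 0.953 between tumour libraries of different groups.

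Model against Control asks how the untreated tumour differs from normal lung. Hmga2, Rhox5 and Myc rose in the tumour tissue, and marker genes of the alveolus and airway were nearly lost. Hmga2, a fetal chromatin protein, had 468 ± 49.2 CPM in Model and 0.113 ± 0.152 CPM in Control (SD, n = 3), and the X-linked homeobox gene Rhox5 had 326 ± 12.9 and 0.458 ± 0.611 CPM. Myc rose from 9.63 ± 0.199 to 423 ± 79.8 CPM, a log2 fold change of 5.46 (SE 0.18, adjusted p = 1.88e-09 in edgeR's quasi-likelihood test). Sftpc, a surfactant protein of alveolar type 2 cells, fell from 16046 ± 1108 to 1.24 ± 2.10 CPM, and Scgb1a1, the main secretoglobin of airway club cells, from 35408 ± 6558 to 26.6 ± 43.8 CPM.

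In this comparison 13479 of 23191 genes passed the threshold, 6688 higher and 6791 lower in Model. Of these, 8784 differed by more than 2-fold, 3686 higher and 5098 lower. The group values of 68.9% of the genes tested did not overlap, where chance gives 10%. DESeq2 called 13839 genes, voom with library weights 15179 and limma on log2(FPKM + 1) 11566. The other genes with the largest rises were Dkk2, a Wnt antagonist (log2 fold change 8.21), the transcription factor Osr2 (8.98), Hmga1 (5.04) and the arginase gene Arg1 (6.53, from 2.46 ± 1.07 to 227 ± 30.1 CPM). Rhox2d, Rhox2h and Rhox2g had 0 counts in Control and were at least 2678-fold, 2958-fold and 1966-fold higher in Model, with the reservation that these near copies may share reads. The other largest falls were the surfactant genes Sftpb (−13.43) and Sftpa1 (−11.95), the phosphate carrier Slc34a2 (−12.31), the lung chemokine Cxcl15 (−13.35), the methyltransferase Inmt (−9.25), Wfdc2 (−8.33), and the club-cell genes Cyp2f2 (−9.11) and Scgb3a2 (−8.19). The Model libraries differed among themselves in these lung genes, and their SE was 1.35 to 3.27 in this group, so the size of the fall is less certain than its direction.

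Growth and energy genes were higher. All 24 proliferation genes rose, with a median log2 fold change of 3.66 (camera adjusted p = 1.45e-38; adjusted p = 0.0808 with an estimated correlation). Bub1 (3.77) and Mcm5 (3.25) were its members with the smallest p. Of 17 glycolysis and hypoxia genes, 15 rose, among them Eno1 (3.6) and Pkm (3.01), while Vegfa fell by 4.09 on the log2 scale (list adjusted p = 1.49e-08; adjusted p = 0.347 with an estimated correlation). Of 26 oxidative phosphorylation genes, 17 rose and 3 fell, with a median of 0.34 (adjusted p = 0.0285; adjusted p = 0.739 with an estimated correlation). In the amino acid stress response, 8 of 16 genes rose, led by the serine synthesis genes Phgdh (4.46) and Psat1 (3.67), and 6 fell, among them Ddit3 (−1.03), with an adjusted p of 6.8e-04 (adjusted p = 0.331 with an estimated correlation).

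The genes that make or move taurine and proline changed in both directions. Slc6a6, the taurine transporter, rose from 136 ± 14.4 to 265 ± 20.2 CPM (log2 fold change 0.96, adjusted p = 2.53e-06), and Pter rose by 1.96 on the log2 scale. Cdo1, which starts taurine synthesis from cysteine, fell from 137 ± 22.1 to 4.60 ± 2.12 CPM, and Fmo1, which makes taurine from hypotaurine, fell by 7.47 on the log2 scale. Of the 12 taurine genes, 5 rose and 4 fell, and the list was not called (adjusted p = 0.670; the median was 0.51 and the mean −0.50). Aldh18a1, the first enzyme of proline synthesis, rose from 12.8 ± 1.38 to 122 ± 6.57 CPM, while Oat (−1.40) and the proline-degrading Aldh4a1 (−2.38) fell. Of the 16 proline genes, 5 rose and 5 fell (list adjusted p = 0.982; median −0.26 and mean −0.64, though the test's direction was up).

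Matrix genes were split. Procollagen-modifying enzymes were mostly higher, 9 of 14, including Plod1 (2.37) and Crtap (1.70), and 3 fell, including P4ha2 (−1.88) (adjusted p = 0.00600; adjusted p = 0.474 with an estimated correlation). Of 14 mesenchymal transition genes, 7 rose, including Mmp14 (2.75) and Vim (2.15), and 5 fell, including Mmp2 (−2.59) (adjusted p = 0.00491; adjusted p = 0.331 with an estimated correlation). Among 23 collagens and matrix genes, Thbs2 (6.09) and Fn1 (3.36) were among 9 that rose, and Postn (−4.64) and Sparc (−1.39) among 10 that fell (adjusted p = 0.167; median −0.23 and mean 0.14). Of 13 antioxidant genes, Gsr (1.77) was among 5 that rose and Gstm1 (−3.09) was 1 of 2 that fell (adjusted p = 0.476; median 0.28 and mean −0.07).

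Markers of normal lung cells were lower together. All 9 alveolar type 2 genes (median −11.77, adjusted p = 6.8e-04), all 8 alveolar type 1 genes (median −6.66, adjusted p = 2.82e-08), all 11 ciliated-cell genes (median −7.59, adjusted p = 0.00761) and all 11 endothelial genes (median −4.47, adjusted p = 2.28e-09) fell. With an estimated correlation these had adjusted p = 0.347, 0.0568, 0.347 and 0.331. Hopx (−5.28), Tppp3 (−5.47), Calcrl (−6.07) and Tek (−6.64) are examples. Of 12 epithelial genes 10 fell, including Krt19 (−6.05), and Krt18 did not pass (0.30), with an adjusted p of 0.00572. Of 10 fibroblast genes 8 fell, including Npnt (−6.24) and Pdgfra (−1.09), with an adjusted p of 0.00195. With an estimated correlation both lists lost their call (adjusted p = 0.511 and 0.347). The club and secretory list (5 of 7 lower, adjusted p = 0.162), cardiac muscle (6 of 9 lower, adjusted p = 0.0509) and mesothelium (4 of 7 lower, 1 higher, adjusted p = 0.162) were not called. Neither were skeletal muscle (5 of 10 higher, adjusted p = 0.402), adipocytes (1 of 6 higher, adjusted p = 0.840), thymocytes (1 of 3 lower, adjusted p = 0.840; median 1.02, test down), basal and squamous epithelium (0 of 6 passing, adjusted p = 0.982) and cartilage (0 of 2 passing, adjusted p = 0.911).

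Immune genes moved in different directions. Of 14 tumour-associated macrophage genes 13 rose, including the complement genes C1qc (2.96) and C1qb (2.90), with a median of 2.59 (adjusted p = 1.12e-06; adjusted p = 0.218 with an estimated correlation). The chemokines Ccl2 (5.42) and Cxcl1 (4.50) rose, but the list of inflammatory cytokines had 4 higher and 5 lower genes of 14 (adjusted p = 0.933). All 9 class I presentation genes fell, such as H2-K1 (−2.95, from 1608 ± 199.6 to 208 ± 31.3 CPM; list adjusted p = 0.0123), and so did all 7 class II genes (median −3.99, adjusted p = 0.0393) and 12 of 17 interferon response genes, such as Ifit3 (−3.52; list adjusted p = 0.0285). With an estimated correlation these had adjusted p = 0.703, 0.739 and 0.741. The class II call was also lost without Model 3 (adjusted p = 0.0528) or Taurine 3 (0.0583), and the interferon call when 3 libraries were left out together (0.140). Of the cytotoxic and natural killer (NK) genes 10 of 13 fell, including Gzma (−5.95; list adjusted p = 0.0217), and of the B and plasma cell genes 10 of 11, including Ms4a1 (−5.28; adjusted p = 0.00342). Of the erythroid genes 5 of 7 fell, including Hbb-bs (−4.05; adjusted p = 0.00656). With an estimated correlation they had adjusted p = 0.583, 0.455 and 0.455. T-cell genes (6 of 12 lower, adjusted p = 0.159), alveolar macrophage genes (6 of 8 lower, Marco higher by 1.96, adjusted p = 0.104) and neutrophil genes (2 higher and 1 lower of 12, adjusted p = 0.840) were not called as lists. Among 13 checkpoint genes Cd276 rose (3.54), Tigit rose (1.61) and 4 fell, including Ido1, which had 0 counts in Model and was at least 140.0-fold lower (list adjusted p = 0.976). All 12 immediate early and heat shock genes fell, such as Nr4a1 (−5.58; list median −3.42, adjusted p = 5.8e-10; adjusted p = 0.118 with an estimated correlation). Adjusted over the list alone, the counts were the same as over all genes in most of these lists. They were 11 higher for procollagen modification, 8 higher for mesenchymal transition, 11 lower for collagens and matrix, 3 lower for antioxidant genes, 1 higher and 2 lower for checkpoints, 1 higher for neutrophils, 1 higher for fibroblasts, 7 lower for cardiac muscle and 5 lower for mesothelium.

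**Figure D1:**
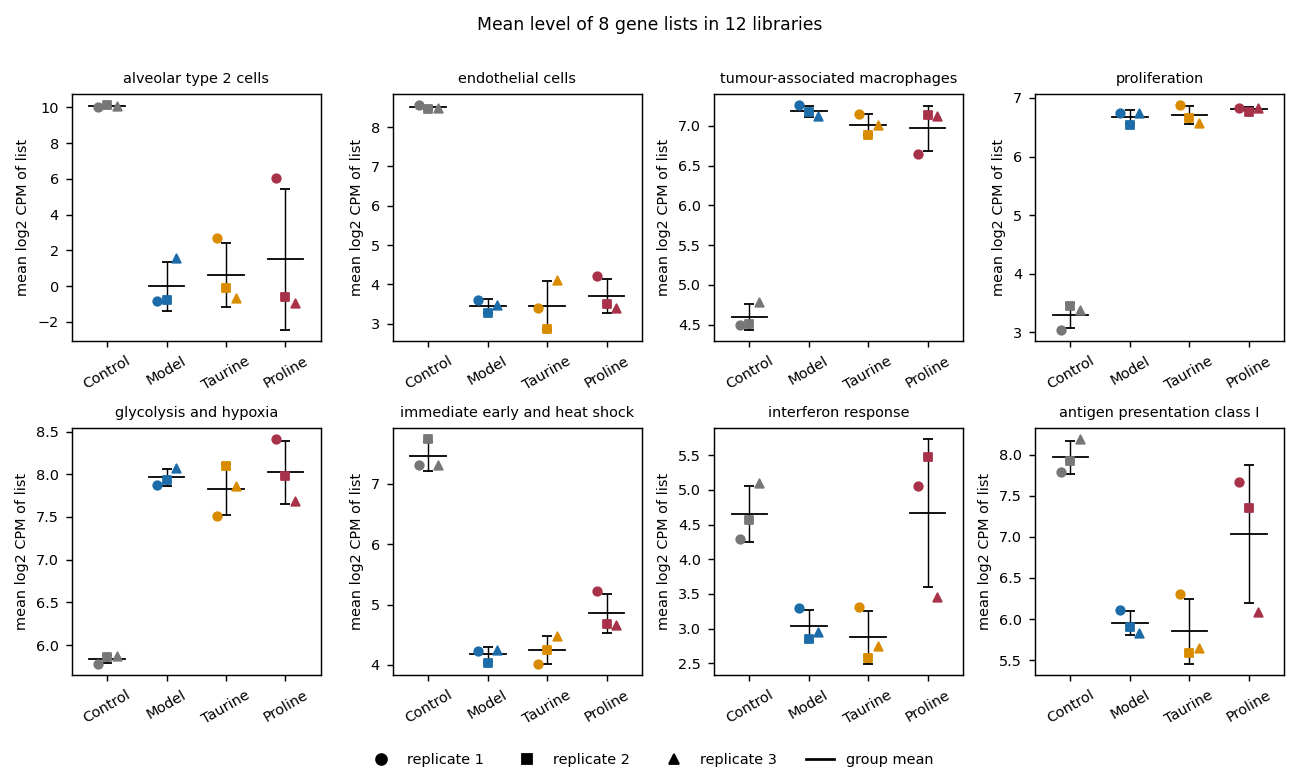
Mean log2 CPM of 8 gene lists in each of the 12 libraries, with group means and whiskers of 1 SD (n = 3). The interferon list stood at 5.06 and 5.48 in Proline 1 and 2 and at 3.46 in Proline 3.

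Taurine against Model asks what taurine treatment changed in the tumour. The T-cell, B-cell and red-cell marker lists were at lower levels in the taurine-treated tumours by camera with its preset correlation, but not with an estimated one, and no single gene passed the threshold. The haemoglobin gene Hbb-bs had 28.3 ± 14.9 CPM in Taurine and 92.0 ± 21.5 CPM in Model, and the immunoglobulin light chain gene Igkc 18.1 ± 14.7 and 57.3 ± 18.2 CPM. The T-cell receptor subunit gene Cd3d had 0.108 ± 0.138 and 1.82 ± 1.77 CPM (n = 3 each). The taurine transporter Slc6a6 stood at 273 ± 13.4 and 265 ± 20.2 CPM.

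By edgeR's quasi-likelihood test 0 genes passed, with a smallest adjusted p of 0.145 and 1574 genes at an unadjusted p under 0.05, where 1160 are expected by chance. DESeq2 called 88 genes, voom with library weights 0 and limma on log2(FPKM + 1) 1. The groups did not overlap for 11.8% of the genes, where chance gives 10%. The genes with the smallest p, none passing, were Samd12 (log2 fold change 2.25, adjusted p = 0.145), Arc, Efcab12, Tmem269 and Gzme, which had 0 counts in Model and were at least 12.9-, 11.6-, 11.2- and 45.0-fold higher in Taurine, and, on the lower side, Cdc42ep2 (−0.72), Bcl11a (−2.59), Cdc42se1 (−0.30), Ankzf1 (−0.47) and Cimip3, which had 0 counts in Taurine and was at least 17.1-fold lower. Cdo1 (−1.01), Csad (−0.19), Slc36a1 (−0.12), Prodh (−0.07), Pycr1 (0.16), Aldh18a1 (0.05), Slc6a20a (−0.28), Cd274 (−0.16) and Mki67 (0.13) did not pass, with adjusted p of 0.705 to 1.

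Camera called 7 of the 37 lists, and 0 of them with an estimated correlation. Fry called 0 lists. The T-cell list was lower (median −1.82, all 12 members below 0, 1 lower adjusted over the list alone, adjusted p = 4.38e-11; adjusted p = 0.383 with an estimated correlation), with Cd5 at 0 counts in Taurine and at least 57.8-fold lower. Thymocyte transcripts, a list not called (adjusted p = 0.141), were also highest among the tumours in Model 1, which had the highest T-cell level of the Model libraries. The thymocyte gene Rag1, chosen after its values were seen, had 2.74, 0.473 and 0 CPM in Model and 0 CPM in every Taurine library, so thymic tissue in Model 1 was not ruled out as part of the T-cell difference. The B and plasma cell list (median −1.18, 0 members adjusted over the list alone, adjusted p = 3.25e-09) and the erythroid list (median −1.69, 5 of 7 lower adjusted over the list alone, adjusted p = 7.27e-15) were lower too, with Jchain (−1.18) and Hba-a1 (−1.69) as further members (adjusted p = 0.268 and 0.113 with an estimated correlation). The alveolar macrophage list was lower (median −0.55, adjusted p = 0.0245; adjusted p = 0.268 with an estimated correlation), with 1 higher and 3 lower adjusted over the list alone, such as Plet1 (1.31) and Marco (−1.22). Its mean was −2.09, and 4 of its 8 members were above 0. Its member Fabp1, a liver and gut gene, had 0 counts in Taurine and was at least 276-fold lower. Fabp1 also had 0 counts in Model 3, so this call may partly reflect the liver transcripts of Model 1 and 2. Neutrophil genes were lower (median −0.58, adjusted p = 0.0288) and cytotoxic and NK genes higher (median 0.07, adjusted p = 0.0288), with Ltf (−3.94) and Prf1 (1.91) among them, and both lost their call with an estimated correlation (adjusted p = 0.959 and 0.936). Skeletal muscle genes were higher (median 1.89, adjusted p = 0.0236; adjusted p = 0.959 with an estimated correlation), and Myh4 had 44.3 ± 66.7 CPM in Taurine and 5.77 ± 5.94 CPM in Model. None of the other 30 lists was called, interferon response (adjusted p = 0.425), proliferation (0.485), taurine synthesis (0.377) and proline metabolism (0.949) among them.

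The weaker list calls ended when single libraries were left out. Skeletal muscle had an adjusted p of 0.993 without Taurine 3 and 0.285 without Model 3, neutrophils 0.665 without Model 1 and 0.289 without Taurine 3, and cytotoxic and NK genes 0.877 without Taurine 1. Leaving out any Control library also ended the calls of these 3 lists and of alveolar macrophages (adjusted p = 0.0675 to 0.104), as did Model 1 (0.0518) or Taurine 2 (0.0568) for alveolar macrophages, and Model 2 for cytotoxic (0.0603) and muscle genes (0.0673). The Control libraries are not part of this contrast, and each such run filtered genes anew. Whether the losses came from the filter, the fitted spread or the library itself was not tested. The T-cell, B-cell and erythroid lists kept their call without each library, but the T-cell and B-cell calls ended with a term for the sets of libraries that hold liver or kidney transcripts (adjusted p = 0.446 and 0.132). So did those of alveolar macrophages (0.0903), neutrophils (0.846) and cytotoxic and NK genes (0.206), and 6 lists were called, 2 of the original 7 among them. The term was chosen after seeing the data, and with it the comparison rests on Model 3 alone on the Model side. The number of called lists was 3 without any 1 of the Control libraries, 11 without Taurine 1 and 12 without Taurine 2. Without Model 3, 7 genes passed, and without Taurine 1, 1 gene, Samd12.

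Proline against Model asks the same of proline. The interferon-inducible and antigen-presentation genes stood higher in the proline-treated tumours, but in Proline 1 and 2 and hardly in Proline 3. Cd274, which encodes the checkpoint ligand PD-L1, had 33.8, 65.3 and 11.9 CPM in the Proline libraries and 13.1 ± 2.21 CPM in Model (SD, n = 3). Gzmb, the granzyme of cytotoxic lymphocytes, had 21.4, 22.2 and 4.14 CPM against 1.23 ± 0.556 CPM, and the class I gene H2-K1 had 744, 453 and 241 CPM against 208 ± 31.3 CPM. The immediate early gene Junb was higher, at 128 ± 11.7 against 67.8 ± 14.5 CPM. The list of immediate early and heat shock genes was fixed in advance for handling, and a handling difference was not ruled out. None of these genes passed the threshold.

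EdgeR's quasi-likelihood test called 0 genes, with a smallest adjusted p of 0.0771 and 3106 genes at an unadjusted p under 0.05, where 1160 are expected. DESeq2 called 769 genes (484 higher and 285 lower), voom with library weights 59 and limma on log2(FPKM + 1) 1. The groups did not overlap for 18% of the genes, where chance gives 10%. The genes with the smallest p, none passing, were Samd12 (2.41), Flrt3 (2.86), Cnn2 (0.58), Junb (0.92) and Arc, at least 35.4-fold higher against 0 counts in Model, and Entpd4b (−0.72), Trp53inp2 (−0.63), Ggact (−0.76), Pck1 (−4.35) and Eci3, at least 51.2-fold lower with 0 counts in Proline. Of the genes fixed in advance, Slc6a6 (−0.21), Slc36a1 (−0.20), Prodh (0.11), Pycr1 (0.14), Aldh18a1 (0.04), Slc6a20a (1.40), Cd274 (1.5) and Mki67 (0.02) did not pass, with adjusted p of 0.229 to 0.991. The call count moved with single libraries, to 232 genes without Proline 3, 12 without Model 3, 2 without Taurine 1 and 1 without Taurine 2. The Taurine libraries are not part of this contrast.

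Camera called 13 lists, and 0 of them with an estimated correlation. Fry called 0 lists. All 17 interferon response genes were above 0, such as Oasl2 (1.80) and Bst2 (1.41), with a median of 1.74 (adjusted p = 1.19e-20; adjusted p = 0.165 with an estimated correlation), and 16 were higher adjusted over the list alone. All 9 class I genes were higher adjusted over the list alone, such as B2m (1.22) and Psmb8 (1.54), with an adjusted p of 6.59e-12 (adjusted p = 0.220 with an estimated correlation). Cytotoxic and NK genes (median 2.13, 5 of 13 higher adjusted over the list alone, adjusted p = 4.48e-11), inflammatory cytokines (median 1.14, 6 of 14, adjusted p = 2.6e-08) and immediate early and heat shock genes (median 0.85, 6 of 12, adjusted p = 9.23e-11) were higher, with Gzma (3.52), Il1b (2.44) and Egr1 (1.05) as examples. With an estimated correlation these had adjusted p = 0.165, 0.266 and 0.165. The checkpoint list (median 0.67, 3 of 13 higher adjusted over the list alone, adjusted p = 0.00271) and the class II list (median 1.62, 0 of 7, adjusted p = 9.1e-04) were higher, with Havcr2 (0.82) and Cd74 (1.93) as members (adjusted p = 0.569 and 0.625 with an estimated correlation).

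Also called as higher were proliferation (median 0.13, adjusted p = 0.00719), the amino acid stress response (median 0.17, adjusted p = 0.00695) and neutrophils (median 0.89, adjusted p = 0.0324), each with 0 members adjusted over the list alone, such as Mcm4 (0.30), Mthfd2 (0.54) and S100a8 (1.31). With an estimated correlation these had adjusted p = 0.794, 0.450 and 0.794. Lower lists were adipocytes (median −1.69, adjusted p = 2.06e-06), erythroid cells (median −0.26, adjusted p = 0.0253) and taurine synthesis and transport (median −0.20, adjusted p = 0.0232), each with 1 gene lower adjusted over the list alone. They had adjusted p = 0.165, 0.656 and 0.326 with an estimated correlation. Adipoq (−2.35), Slc4a1 (−4.93), Csad (−0.43) and Cdo1 (−1.0) are members. The taurine list stood at 3.23 and 3.27 mean log2 CPM in Model 1 and 2, 2.81 in Model 3 and 2.27 to 2.77 in Proline. Model 1 and 2 also held liver transcripts, and their part in the taurine list's call was not tested on its own. Of the 24 other lists, alveolar type 2 genes had 7 of 9 higher adjusted over the list alone (adjusted p = 0.0932), with Sftpc highest in Proline 1. The club and secretory list had a median of −1.59 while its test pointed up (adjusted p = 0.969), and proline metabolism was not called (adjusted p = 0.947).

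Without Proline 1 the class II (adjusted p = 0.292), checkpoint (0.0748) and neutrophil (0.470) lists lost their call. Proliferation lost it without Model 2 (0.204), stress without Proline 2 (0.0594), and taurine synthesis without Proline 3 (0.110) or Control 2 (0.0556). The neutrophil call was also lost without Proline 2 (0.260), Model 2 (0.185), Model 3 (0.184) or any Control library, and the erythroid call without Model 2 (0.114), Proline 3 (0.0542) or any Control library (0.0597 to 0.0851 over both lists). The interferon, class I, cytokine, cytotoxic, immediate early and adipocyte lists kept their call without each library. With the term for liver and kidney sets the immediate early (0.127), checkpoint (0.0950) and taurine synthesis (0.150) calls ended. The erythroid list turned to higher (0.0148), in a comparison that then rests on Model 3 and the Taurine libraries. With 3 libraries left out, the calls of proliferation (0.365), stress (0.146), class II (0.371), checkpoints (0.251), neutrophils (0.874) and erythroid cells (0.225) ended. Both settings were chosen after seeing the data.

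**Figure D2:**
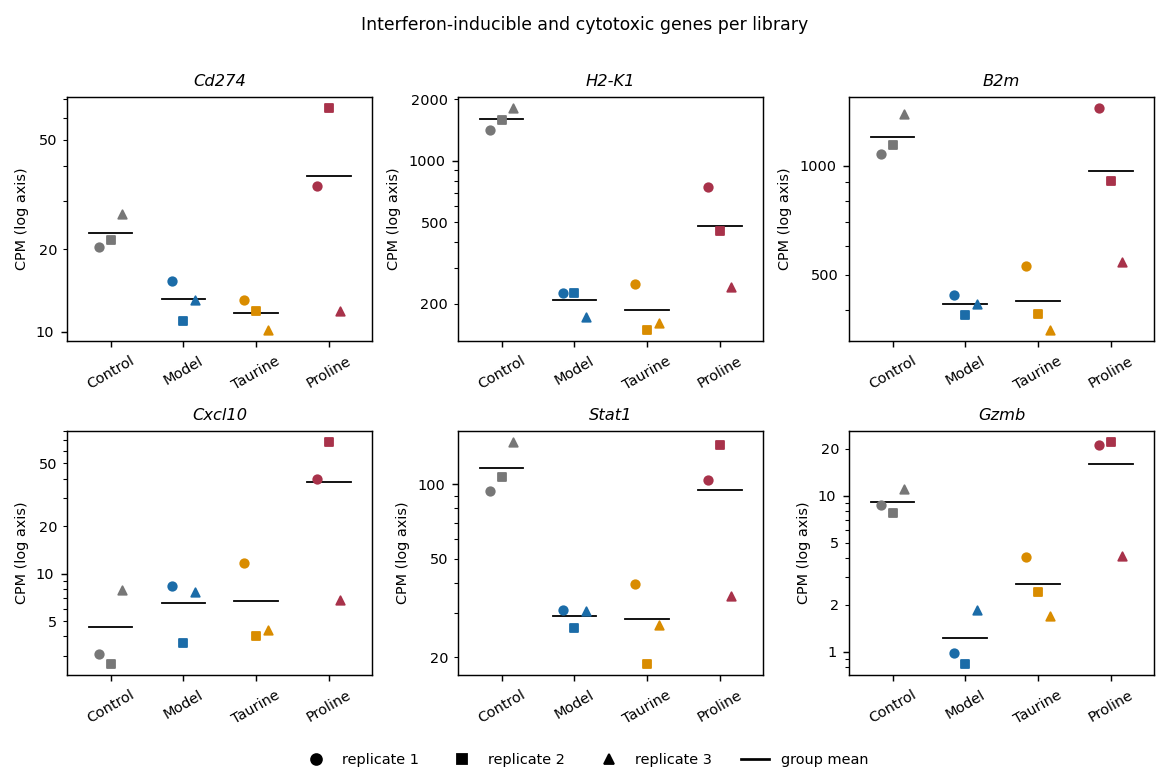
Normalised CPM (log axis) of 6 interferon-inducible or cytotoxic genes in each library, with a bar at the group mean (n = 3). Cd274 stood at 33.8 and 65.3 CPM in Proline 1 and 2 and at 11.9 CPM in Proline 3.

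Transcripts of other tissues differed between tumour libraries of the same group. The mean log2 CPM of the skeletal muscle list was 5.43, 2.92 and 1.47 in the Model libraries, 4.35, 2.69 and 7.44 in Taurine, and −1.14, 5.64 and 5.38 in Proline. A set of 6 lung-restricted genes stood at 3.99% of its Control level in Proline 1 and at 0.00151% to 0.148% in the other tumour libraries. The liver gene Alb had 76.1 and 95.5 CPM in Model 1 and 2, and 0 to 0.197 CPM in the other tumour libraries. The kidney gene Kap had 33.2 CPM in Model 3, 29.2 and 33.0 CPM in Taurine 1 and 2, and 0.786 to 6.38 CPM in the other tumour libraries. Pck1, which liver, kidney and fat express, had 6.71, 17.6 and 13.1 CPM in Model and 0.713, 0.322 and 0.784 CPM in Proline. Fabp1, a liver and gut gene that the alveolar macrophage list holds, had 5.32 and 6.84 CPM in Model 1 and 2 and 0 CPM in all other tumour libraries.

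**Figure D3:**
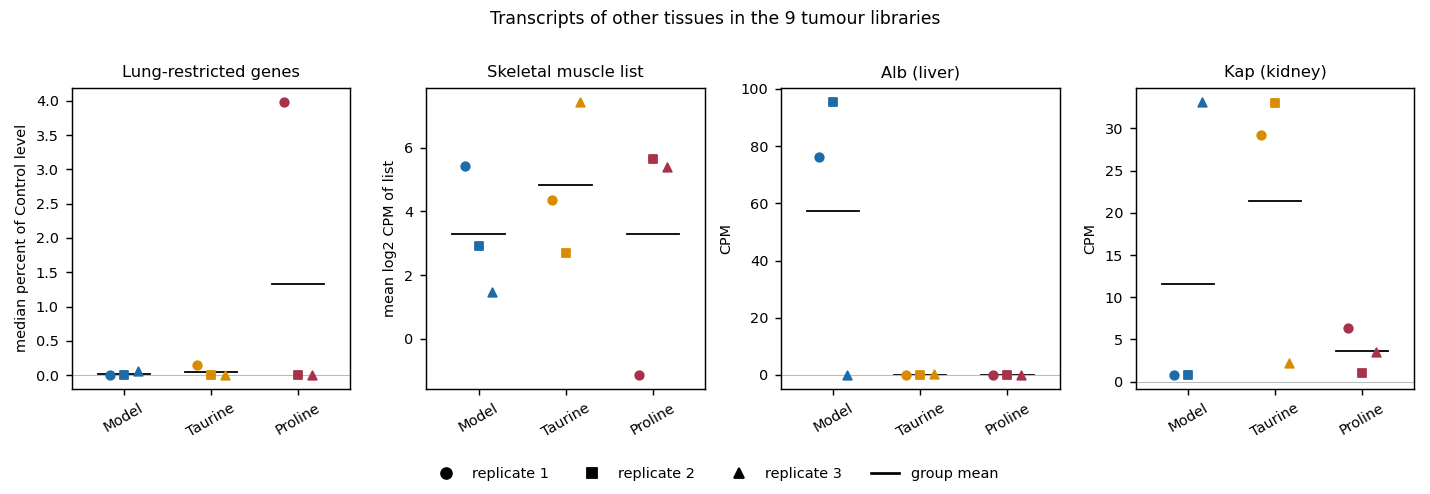
Lung-restricted genes (median percent of the Control level), the skeletal muscle list (mean log2 CPM), Alb and Kap (CPM) in the 9 tumour libraries, with a bar at the group mean (n = 3). Alb stood at 76.1 and 95.5 CPM in Model 1 and 2, and Kap at 33.2 CPM in Model 3.

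Taurine against Proline asks whether the treatments differ from each other. The TGF-beta co-receptor gene Tgfbr3 was at 447 ± 49.99 CPM in Taurine and 287 ± 7.32 CPM in Proline (SD, n = 3), and the cytoplasmic actin gene Actg1 at 1309 ± 92.3 and 1930 ± 53.3 CPM. In Model they stood at 397 ± 21.5 and 1424 ± 85.1 CPM. The interferon, class I and T-cell lists were lower in Taurine than in Proline by camera, but lost their call with an estimated correlation (adjusted p = 0.223 each), and fry called none.

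In this comparison 10 genes passed, 7 higher and 3 lower in Taurine, and the groups of 16.8% of the genes did not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 3334 genes. DESeq2 called 1075 genes (457 higher and 618 lower), voom with library weights 101 and limma on log2(FPKM + 1) 17, of which 10, 9 and 6 were among the 10. Higher in Taurine were Tgfbr3 (log2 difference 0.64, SE 0.08), the autophagy SNARE gene Stx17 (0.50), Dclk2 (0.57), Dennd1b (0.51), Wasf3 (1.74), Trp53inp2 (0.61) and Entpd4b (0.66), and lower were Actg1 (−0.56), Snx20 (−1.43) and Spmip6 (−3.61). Their adjusted p-values were 0.0421 or 0.04997, just under the threshold. The count moved with single libraries, to 312 without Proline 3 (64 higher and 248 lower), 51 without Taurine 1, 1 without Taurine 2 (Spmip6) and 0 without any of the other 9 libraries. These 9 include the Control and Model libraries, which are not part of this contrast, and each run filtered genes anew. Camera called 14 lists, 13 lower and 1 higher in Taurine, and 0 of them with an estimated correlation, and fry called 0. Without Proline 2 camera called 24 lists. The interferon list had a median difference of −1.94, and 15 of its 17 genes were lower adjusted over the list alone.

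**Figure D4:**
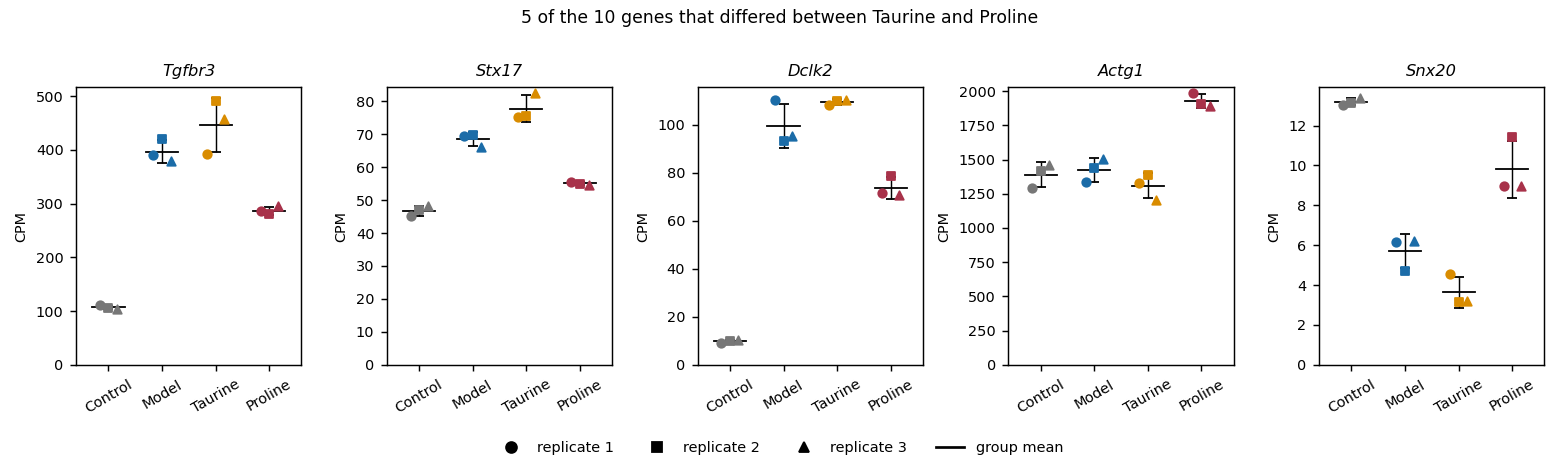
Normalised CPM of 5 of the 10 genes that differed between Taurine and Proline, in all 4 groups, with group means and whiskers of 1 SD (n = 3). Stx17 stood at 77.8 ± 3.98 CPM in Taurine and 55.0 ± 0.523 CPM in Proline.

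The taurine and proline fold changes against Model had a correlation of 0.491 across genes, which are not independent replicates. Simulated unchanged groups, with the Model libraries also drawn from the Model means, gave a mean of 0.498 (0.475 to 0.526 over 50 simulations). The share of genes with the same sign was 62.9% against a simulated 66.4%. The covariance was 0.257 against a simulated 0.188, and the spread of the real Model libraries alone gives 0.223. With 0 calls in both comparisons there is no overlap of called genes. The 3 Model libraries cannot be split into parts of at least 2, so part of any excess may come from the shared libraries. Between Taurine and Control 13879 genes differed, and between Proline and Control 13462, as treated tumour is set against normal lung there. Of these, 12427 and 12001 were also called in Model against Control, but all these comparisons share the same Control libraries and no value for unchanged treatment was computed, so the overlap says nothing about treatment.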

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

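Tests of residual lung and of liver and kidney transcripts were chosen only after the results were seen, and the leukocyte test and the splits of the samples were chosen before. The results here are differences between the effects of taurine and proline, tested directly as Taurine against Proline, in which the Model libraries cancel. With 3 libraries per group, no test for a single sample far from the others was made.

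Taurine and Proline differed in 10 genes by edgeR's quasi-likelihood test, 7 higher and 3 lower in Taurine. The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. Of the 10 splits, 1 gave as many genes, the real one, and the highest other split gave 3.

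Camera called 14 lists as different, and none of them was called with an estimated correlation, for which the adjusted p is given after each median log2 difference, Taurine minus Proline. Interferon response differed by −1.94 (0.223), class I presentation by −1.36 (0.223), class II by −1.94 (0.311), immune checkpoints by −0.77 (0.292) and inflammatory cytokines by −1.20 (0.223). Immediate early and heat shock genes differed by −0.66 (0.223), the amino acid stress response by −0.25 (0.223) and glycolysis and hypoxia by −0.14 (0.769). T-cell markers differed by −3.08 (0.223), cytotoxic and NK by −1.57 (0.223), B and plasma by −1.27 (0.223), neutrophil by −1.45 (0.364) and erythroid markers by −1.43 (0.278), and adipocyte markers by 1.46 (0.239). The thymocyte gene Rag1, chosen after its values were seen, had 1.06 CPM in Proline 2 and 0 CPM in Proline 1, Proline 3 and every Taurine library, so thymic tissue in Proline 2 was not ruled out as part of the T-cell difference. For the erythroid list the mean was 0.08, of the other sign than the median. Adjusted over the list alone, 15 of 17 interferon, 9 of 9 class I, 7 of 7 class II, 9 of 14 cytokine, 8 of 12 T-cell, 4 of 12 immediate early, 4 of 11 B-cell, 3 of 13 checkpoint, 2 of 16 stress, 2 of 12 neutrophil, 2 of 13 cytotoxic and 0 of 17 glycolysis genes were lower in Taurine. Of the erythroid genes 1 was higher and 5 were lower, and 1 of 6 adipocyte genes was higher. The glycolysis call was past the threshold in 11 of 16 alternatives that keep the fixed correlation. Among others, it ended without Taurine 1 (camera adjusted p = 0.456) or Proline 1 (0.717), with 3 libraries left out (0.816) and with the liver and kidney sets as a term (0.0617). The checkpoint call ended with the sets as a term (0.0627; up to 0.124 over the alternatives that keep the fixed correlation, 13 of 16 past the threshold). Class II (0.111) and adipocytes (0.816) lost their call with 3 libraries left out, a setting chosen after seeing the data, as was the term, under which Taurine 3 alone is compared with the Proline libraries.

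The interferon and class I genes are weighed further, as the pattern of Proline against Model. Their level was high in Proline 1 and 2, with interferon list means of 5.06 and 5.48 log2 CPM against 3.46 in Proline 3 and 2.86 to 3.30 in Model. The tables argue against normal lung RNA left in the pieces as the main source of this pattern. Proline 1 did hold lung-restricted genes, at a median of 3.99% of their Control level. At the share given by lung-restricted genes, normal lung would account for a median of 0.0141% of the excess over Model (quartiles 0.00353% and 4.52% over 52 values), with 4.56% in Proline 1 and 0.00371% in Proline 2. The bound for that explanation was 50%. The estimate uses the interferon and class I levels of Control, so lung with higher levels of these genes is not covered.

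A larger number of leukocytes of all kinds was tested with 12 pan-leukocyte genes. Their median log2 change was 0.41, with an interquartile spread of 0.451, against 1.53 for the 26 interferon and class I genes, which argues against an equal rise of all leukocytes as the whole cause. A shift within the leukocytes stays open, since cytotoxic and NK markers were higher in the same libraries, at 1.31 and 0.65 mean log2 CPM in Proline 1 and 2, −0.55 in Proline 3 and −1.92 to −1.50 in Model. With the liver and kidney sets as a term, which makes Proline against Model rest on Model 3 and the Taurine libraries, the interferon list kept its call (camera adjusted p = 4.08e-08). The range was 6.02e-45 to 4.08e-08 over 16 alternatives that keep the fixed correlation. Fry and camera with an estimated correlation did not call the list. An effect of proline that reached part of the tumours may explain the pattern and stays open as untested, because Proline 3 shows little of it and 3 libraries cannot separate treatment from differences between tumours.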

How the results depend on the processing

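Leaving out 3 libraries together, marker levels as covariates and the liver and kidney sets as a term were chosen after seeing the data. With that term, the comparisons rest on Model 3 (Taurine against Model), Taurine 3 (Taurine against Proline) or Model 3 and all Taurine libraries (Proline against Model). Unless a construction is named, the cause was not tested.

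Model against Control had 13479 genes called, 12401 to 13711 with 1 library left out, and 7230 with an FPKM minimum of 5, where 9016 genes were tested. The share of higher calls was 49.6%, and 58.8% on quantile-normalised values. The count of called lists was 20 (7 higher, 13 lower), 19 to 22 with 1 library left out, 0 with an estimated correlation, 29 by fry, 21 on log2(FPKM + 0.1) (4 higher, 17 lower) and 20 on quantile-normalised values (3 higher, 17 lower). On log2(FPKM + 0.1) and on quantile-normalised values the calls of procollagen modification (adjusted p = 0.0533 and 0.105), mesenchymal transition (0.226 and 0.228) and amino acid stress (0.326 and 0.343) ended, and on the latter that of oxidative phosphorylation (0.0965).

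Taurine against Model had 0 genes called (1574 at an unadjusted p under 0.05), and 0 to 7 with 1 library left out. DESeq2 called 88. Limma on log2(FPKM + 1), on quantile-normalised values and without trend and robust each called 1, Gm22513. With 3 libraries left out 1 was called, Gm28042. With the liver and kidney sets as a term 5 were called, Nnt, Ndor1, Or7d10, Zfp1003 and Gm49450. These names were chosen after their values were seen. Nnt is listed under 2 IDs, and in Model 3 the first held 89.2 CPM and the other 0, while their sum was 76.4 to 89.2 CPM over Model, so that call comes from how reads were split between IDs. The count of called lists was 7, and 3 to 12 with 1 library left out (3 to 7 of the original 7 among them), 0 with an estimated correlation, 0 by fry, 4 on log2(FPKM + 0.1), 4 on quantile-normalised values and 14 with 3 libraries left out. The muscle list reversed to lower with 3 libraries left out (adjusted p = 0.561; 1.95e-05 to 0.993 over 16 alternatives that keep the fixed correlation), and Taurine 3, its highest library, is among those left out.

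Proline against Model had 0 genes called (3106 at an unadjusted p under 0.05), and 0 to 232 with 1 library left out. DESeq2 called 769 and voom with library weights 59. Limma on log2(FPKM + 1) and on quantile-normalised values called 1, Osr2, and without trend and robust 2, Osr2 and Ggact. With 3 libraries left out 3 were called, 4933427D14Rik, Ccn5 and Raver2, and with the sets as a term 6. The count of called lists was 13, and 10 to 19 with 1 library left out (10 to 13 of the original 13 among them), 0 with an estimated correlation and 0 by fry. On log2(FPKM + 0.1) it was 10 and on quantile-normalised values 11, each with 10 of the original 13. Checkpoints and taurine synthesis were each past the threshold in 11 of 16 alternatives that keep the fixed correlation. The erythroid list reversed to higher with the sets as a term (adjusted p = 0.0148; 0.00560 to 0.691 over the same 16 alternatives).

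Taurine against Proline had 10 genes called, and 0 to 312 with 1 library left out. There were 0 with no filter, with median-ratio scaling, with only the compared groups, without mitochondrial and similar genes, with marker covariates and with the sets as a term. An FPKM minimum of 5 gave 32 (15 higher and 17 lower), limma on log2(FPKM + 1) 17, on log2(FPKM + 0.1) 3, and without trend and robust 16, voom with library weights 101 and DESeq2 1075. With 3 libraries left out there were 2, 4933427D14Rik and Gm28042. The count of called lists was 14, and 14 to 24 with 1 library left out (13 or 14 of the original 14 among them), 0 with an estimated correlation and 0 by fry. On log2(FPKM + 0.1) it was 13 and on quantile-normalised values 12, all of them among the original 14. The correlation of taurine and proline fold changes was 0.491, 0.414 on log2(FPKM + 0.1), and 0.39998 to 0.626 with 1 library left out.

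Among named genes, 1498 of 1538 alternatives in Model against Control stayed on the same side of the threshold, with 13 weaker and 27 stronger. In the other comparisons 481 of 499, 680 of 730 and 503 of 647 did, in the order above. In these totals the runs with 1 library left out count once per gene, by the run that changed it most. No gene past the threshold reversed. In 120 alternatives over all comparisons, with each such run counted, a named gene that did not pass changed sign. Aside from the estimated correlation, called lists kept their call and direction in 310 of 320, 78 of 119, 174 of 221 and 214 of 238. At 56542745 or more counts per library, simulated 1.5-fold changes, made only in genes above a minimum Model level, were recovered at 26% to 36%. The effect of depth on the calls was not tested. All alternatives fixed before the data were seen were run, with library weights estimated inside voom.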

Other observations

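Tests of muscle, of ribosomal RNA and of liver and kidney sets, and the use of KEGG pathways, were chosen after the results were seen, and the tests of shared libraries, of tissue genes and of sample splits before. Camera over 241 KEGG pathways called 30 higher and 31 lower in Model than in Control, and none with an estimated correlation. DNA replication (33 of 36 genes higher, median log2 fold change 1.71, adjusted p = 4.14e-19), Ribosome (125 of 172, median 1.01), Ribosome biogenesis in eukaryotes (61 of 76, median 0.95) and Aminoacyl-tRNA biosynthesis (35 of 44, median 0.86) were higher. Homologous recombination (31 of 41) and Mismatch repair (20 of 24) were higher too. Axon guidance (89 of 162 lower, median −0.99), Cell adhesion molecules (83 of 146, median −2.25), Vascular smooth muscle contraction (62 of 120, median −1.38) and the cytochrome P450 pathway of xenobiotics (25 of 56, median −2.03) were lower. DNA replication had an adjusted p of 0.348 with an estimated correlation.

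Taurine against Model had 8 pathways higher and 7 lower, led by Cytoskeleton in muscle cells (median 0.25, adjusted p = 1.11e-05) and, lower, Steroid hormone biosynthesis (median −0.20, adjusted p = 0.0156). Proline against Model had 39 higher and 13 lower. Antigen processing and presentation (median 0.54, adjusted p = 1.51e-09), TNF signaling (0.17), IL-17 signaling (0.21) and Ribosome biogenesis in eukaryotes (0.14) were higher, and Steroid hormone biosynthesis (−2.08, adjusted p = 3.99e-08) and Retinol metabolism (−1.19) lower. Taurine against Proline had 6 higher and 30 lower. None was called with an estimated correlation, with adjusted p of 0.905 for the muscle pathway and 0.574 for antigen processing. Liver and kidney express many genes of the steroid and retinol pathways, and their transcripts differed between these libraries.

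Transcripts of muscle, liver and kidney differed between tumour libraries of the same group. The muscle genes rose and fell together. Over the 9 tumour libraries the lowest correlation of a member with the mean of the others was 0.912 (Pearson's r of log2 CPM, Pvalb). Without the 2 farthest libraries the lowest was 0.782 (Myh4), and Pvalb had 0.803. Muscle tissue in some of the sequenced pieces may explain this, but whether the members kept 1 ratio was not computed. Ribosomal RNA left in the libraries did not follow the muscle level. Its share on Rn18s-rs5 gave a Spearman rho of 0.1 (exact permutation p = 0.810) and r of 0.230 (exact permutation p = 0.547), and r was −0.124 without the 2 farthest libraries.

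The liver genes stood out in Model 1 and 2 and the kidney genes in Model 3, Taurine 1 and Taurine 2, and neither in Taurine 3 and the Proline libraries. Within these sets the liver and kidney transcripts had nearly the same level. The median fold between the highest and the lowest library was 1.36 for 11 kidney genes and 1.22 for 12 liver genes, where the muscle list had 6.59 and 4.79 in the same sets. Kidney transcripts stood at even levels across tumours of Model and Taurine. Such RNA may have entered these libraries together, in handling or sequencing, rather than with each tissue piece. The liver set lies within Model, so its even levels do not span groups. The levels were seen before the test was chosen, and the sets were drawn by the median level of these same liver and kidney genes. The muscle genes played no part in drawing them, so the contrast with muscle is weak evidence. Control 1 and 2 held liver transcripts as well, with Alb at 20.1 and 16.9 CPM. Liver or kidney tissue in the tumours was not tested apart from this.

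These sets overlap with the groups, since Model and Proline share none of them. With the sets as a term, 9 of 21123 genes had a set term past the threshold, and 1585 had one at an unadjusted p under 0.05. Against Model, 6 genes were then called for Proline (5 for Taurine), among them Nnt and Ndor1, which are each listed under 2 IDs. The Rn18s-rs5 share was 0.356%, 0.333% and 0.966% in the Model libraries, 0.626%, 0.707% and 1.27% in Taurine and 0.598%, 0.651% and 0.579% in Proline, so Model 1 and 2 also had the lowest ribosomal share of the tumours. Lars2 followed it over the 9 tumour libraries (r = 0.946, exact permutation p = 1.21e-04; rho = 0.967, exact permutation p = 1.65e-04; r = 0.989 without the 2 farthest), at 102 and 117 CPM in Model 1 and 2 and 404 to 820.1 CPM in the other tumour libraries. In Control, Lars2 had 114, 145 and 133 CPM and the Rn18s-rs5 share was 0.200%, 0.238% and 0.262%. In both, Control was nearer to Model 1 and 2 than to the other tumour libraries. Whether Model 3 and the treated libraries were processed apart from these is not given. Lars2 and these relations were chosen after their values were seen.

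The taurine and proline fold changes against Model ran together, with a covariance of 0.257. Simulated unchanged groups, with the Model libraries also drawn from the Model means, gave 0.188 (0.172 to 0.201 over 50 simulations). The spread of the real Model libraries alone gives 0.223, above that range. The observed value lies above all simulated ones, which had been set in advance as the sign of more than shared libraries. That bound was too narrow, since genes were drawn independently, and the jackknife SE of the covariance was 0.187. Shared Model libraries and a shared effect of the treatments cannot be told apart here. Leaving out 436 genes, those of the muscle, alveolar, airway, squamous and adipocyte lists and those that follow the muscle level, moved the correlation from 0.49138 to 0.4915, a fall of −1.17e-04. The correlation was already within the simulated range for unchanged groups (0.475 to 0.526), so there was no excess that this removal could have taken away, and the part of tissue in the pieces stays open.

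The 10 splits of 6 libraries are too few for a share under 0.05. For Model against Control 1 of 10 splits, the real one, gave 13479 genes and the highest other gave 0. For Taurine against Model all 10 gave at least the real count of 0, and the highest other gave 1. For Proline against Model all 10 did as well, with 0 real and 0 in the highest other. In Taurine against Model, the split that set Model 1, Model 2 and Taurine 3 apart had 2491 genes at an unadjusted p under 0.05, against 1574 for the real one, and it sets the 3 kidney libraries against the other 3.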
